A study of Homo sapiens with 2 samples.

How the data were processed

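Polyadenylated RNA of 2 human liver-cancer cell lines, SKHEP1 and HepG2, was sequenced with the PacBio Iso-Seq kit, per the labels' protocols. There was 1 library for each line. The labels give the genotype of both as wild type and the growth medium as the same for both. Reads were aligned to genome build hg38 with minimap2, per the submitters' processing notes. The version of minimap2, the reference annotation and the tool that collapsed reads into isoforms are not given in the sources used here.

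For each library the authors deposited a SQANTI classification table with 1 line for each isoform, and a sheet holding the isoforms at PURPL. Per the file headers, each line gives the isoform's count of full-length reads, which is a raw count with no normalization. The lines also give length and exon number, the reference gene and transcript, a structural category, distances between the isoform's ends and those of the reference, and flags for junctions, template switching and predicted nonsense-mediated decay. The percent of A bases in the 20 nt of genome downstream of the 3′ end is a further column of the deposited table. Full splice match means that all junctions of a reference transcript are present. Incomplete splice match means that a consecutive part of them is present. The catalogue classes outside the reference hold isoforms that recombine known splice sites or that use at least 1 splice site absent from the reference.

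The sign of the end distances was settled from the tables: in 65422 of 65422 full splice matches, isoform length equalled reference length minus both distances, so a negative distance marks an isoform that runs past the reference end. A further 715 lines of the SKHEP1 table and 622 of the HepG2 table are not analysed here. 1 HepG2 isoform with no read was dropped. The smallest count listed was 2 reads in both tables. The totals of 2386656 reads in SKHEP1 and 1876594 in HepG2 are therefore sums over listed isoforms and not the sequencing depth, which is not given in the sources used here. For the same reasons a gene with no line has no valid upper limit, and it is described as having no isoform listed, with no fold. The fixed plan put 3 reads in place of such a gene. That value entered the ranking of genes, the 4-fold calls and the list medians, so a call on such a gene is a convention and no lower limit on its fold. Calls on genes listed in both libraries are counted apart, and list medians over members listed in both are in the closing section.

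Reads were summed by gene over isoforms assigned to 1 gene (full or incomplete splice match, the classes outside the reference, and genic), which held 99.6% of reads in each library. Fusion, antisense and intergenic isoforms entered the library totals only. Gene sums were scaled to RPM, with the total of listed reads as the denominator. With 1 library for each line there is no replicate check, so no p-value was computed, and genes were called by size alone: at least 4-fold with at least 20 reads in the higher library. Ratios have exact conditional binomial 95% intervals, read sums exact Poisson intervals and shares Wilson intervals. All of these cover counting error only, and they may be too narrow even for that. They treat reads as independent molecules, which cannot be checked without molecular identifiers. Shares of isoforms treat isoforms of the same gene as independent. Leading transcripts were compared in genes with at least 20 full-splice-match reads in each library, and a gene was counted where the leading transcript differed and a share differed by at least 50 percentage points.

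Before the data were examined, 16 gene lists were fixed with 437 genes, of which 16 stand in more than 1 list. The list median log2 ratio was taken over members with at least 10 reads in both libraries together. Its percentile was taken among 10000 random lists of the same size matched on mean abundance in 20 bins, as a description of these libraries. The rule for named genes was fixed at the same time: PURPL, the 10 genes with the largest ratio in each direction by the interval bound nearest 1, up to 4 members of each list with the largest ratio, the 8 genes with the largest difference in transcript share with passing members of the epithelial-mesenchymal splicing list, and the 5 most abundant isoforms outside the reference in each line. Values of some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen. Alignment could split reads between near-identical gene copies, so values of ribosomal protein genes, UGT2B7, AKR1C1 and AKR1C3 are uncertain.

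The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data drawn from the pooled means of both libraries. In a simulated SKHEP1 against HepG2 comparison of 12601 genes, 100 of 100 genes changed 8-fold and 0 of 100 changed 2-fold passed the 4-fold rule, as did 0 of 12401 unchanged genes. In the simulated comparison of leading transcripts over 6788 genes, 200 of 200 exchanged genes were recovered and 0 of 6588 others were called. Changed genes were drawn from those with many reads. Exchanged genes also had a wide gap between the leading transcript and the next, so recovery was near certain. The counts had Poisson error only, without a trend with isoform length or variation between libraries. These tests check the computation and give no error rate for the real libraries. Gene types and splice junctions came from GENCODE release 29 on GRCh38, matched by identifier without version, which gave a type for 99.4% of genes. Reference transcripts were compared for junctions only where the exon number was the same in that release and in the tables.

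The alternatives tried were other read minimums, multi-exon isoforms only, full splice matches only, removal of isoforms followed by 60% or more A or carrying the template-switching flag, thinning to equal reads, median-of-ratios scaling, other fold and share limits, and the authors' PURPL sheet. A minimum of 2 reads removes nothing from these tables and so tests nothing. Added after seeing the data were a correction of ratios for their trend with isoform length in 20 bins, list medians over members listed in both libraries, PURPL without isoforms ending before A-rich sequence, lengths without the 10 most abundant genes of each library, and leading transcripts that differ by more than 5 nt at a junction.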

Results

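Full-length transcripts of SKHEP1 and HepG2 were compared, with 1 Iso-Seq library for each line. SKHEP1 is an established line from a liver tumour that the labels describe as endothelial. HepG2 is an established line that the labels describe as hepatocellular carcinoma and that keeps many hepatocyte traits. The stated purpose was to check expression of the long noncoding RNA PURPL and to identify its transcript variants. The SKHEP1 table held 94932 isoforms with 2386656 full-length reads, and the HepG2 table held 79645 isoforms with 1876594 reads. Neither line had a replicate, so every difference below compares 2 libraries, and intervals are 95% intervals for counting error only.

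PURPL, a long noncoding RNA transcribed in response to p53, was listed in both lines, with the same 4 main structures. SKHEP1 had 13 PURPL isoforms with 61 reads (exact Poisson interval 46.7 to 78.4), or 25.6 RPM of listed reads. HepG2 had 11 isoforms with 69 reads (53.7 to 87.3), or 36.8 RPM. The ratio of HepG2 to SKHEP1 was 1.44, with an exact conditional interval of 1.00 to 2.06. By read number PURPL ranked 5338 of 11615 genes listed in SKHEP1 and 4616 of 11197 in HepG2. The gene (ENSG00000250337) lies on the plus strand of chromosome 5 at 27472292 to 27496401 in GENCODE release 29 on GRCh38, where it is annotated as a long intergenic noncoding RNA.

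Most PURPL reads in both lines fell into 3 structures. Isoforms of 2 exons that match the start of PURPL-201 held 22 of 61 reads in SKHEP1 (36.1%, Wilson interval 25.2 to 48.6) and 29 of 69 in HepG2 (42.0%, 31.1 to 53.8). Isoforms of 5 exons that match the start of PURPL-226 held 15 reads in SKHEP1 (24.6%, 15.5 to 36.7) and 16 in HepG2 (23.2%, 14.8 to 34.4). The 4-exon PURPL-221, a full splice match, held 14 reads in SKHEP1 (23.0%, 14.2 to 34.9) and 17 in HepG2 (24.6%, 16.0 to 35.96). The 3-exon PURPL-204 was a full splice match with 4 reads in SKHEP1 and 3 in HepG2. None of these shares differed between the lines beyond its counting interval. In SKHEP1 2 further isoforms retained an intron and had 6 reads together. In HepG2 2 partial matches of 3 exons, to PURPL-224 and PURPL-235, had 4 reads together.

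**Figure D1:**
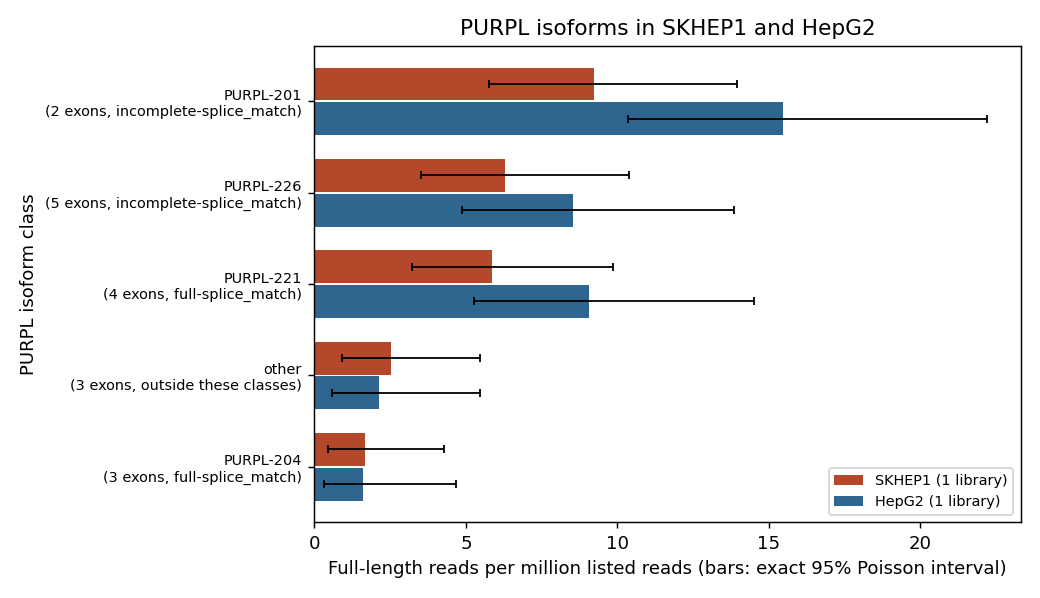
Horizontal bars give full-length reads as RPM for each class of PURPL isoform, in 1 SKHEP1 and 1 HepG2 library, with exact 95% Poisson intervals. The 2-exon class is the largest in both lines (22 reads in SKHEP1 and 29 in HepG2), and the intervals of the lines overlap in every class.

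The 3′ ends of the most abundant 2-exon and PURPL-221 isoforms lay within 2 nt of each other in the lines, relative to the reference, and those of less abundant isoforms varied. The most abundant 2-exon isoform, with 14 reads in SKHEP1 and 19 in HepG2, ended 4399 nt before the reference 3′ end in both, at lengths of 2857 and 2843 nt. The most abundant PURPL-221 isoform ran 3162 nt past the reference end in SKHEP1 (4483 nt long, 10 reads) and 3164 nt past it in HepG2 (4493 nt, 12 reads). Both carried the poly(A) signal AATAAA. PURPL-204 isoforms spanned 27472289 to 27488846 in SKHEP1 and 27472284 to 27488858 in HepG2, so their last exon ran 2700 and 2712 nt past the annotated end. An open reading frame of 100 amino acids, at 27475536 to 27477781, was predicted in PURPL-221 isoforms alone in both lines. All of these isoforms were also predicted to undergo nonsense-mediated decay. Of PURPL reads, 20 of 61 in SKHEP1 (32.8%, 22.3 to 45.3) and 36 of 69 in HepG2 (52.2%, 40.6 to 63.5) came from isoforms whose 3′ end was followed by 60% or more A. Without those isoforms 41 reads remained in SKHEP1 and 33 in HepG2, and the ratio of HepG2 to SKHEP1 was 1.02 (0.627 to 1.66).

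Albumin (ALB), the main protein of blood plasma, was the most abundant gene in HepG2 and held 4.02% of HepG2 reads (Wilson interval 3.996 to 4.05). The transglutaminase TGM2 was the most abundant gene in SKHEP1 and held 1.00% of SKHEP1 reads (0.992 to 1.02). The 10 most abundant genes held 9.48% of reads in HepG2 and 6.19% in SKHEP1. Both lines had ACTB, the cytoplasmic actin, in 2nd place, at 0.724% in HepG2 and 0.924% in SKHEP1. Of 9121 genes with 20 or more reads, 1285 were called higher in SKHEP1 and 1113 in HepG2. Of these, 640 and 658 were listed in both lines and differed at least 4-fold. The other 645 and 455 had no isoform listed in the other line and were called with 3 reads put in its place, which gives no limit on their fold.

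Of the 10 genes furthest above HepG2 in SKHEP1, 7 had no isoform listed in HepG2. They were the intermediate filament gene VIM with 12615 reads, the hyaluronan receptor CD44 with 7194, the lysyl oxidase LOXL2 with 6079, the caveolar coat gene CAV1 with 4323, the protease ADAMTS1 with 4043, the membrane linker MSN with 2938 and MYOF with 2864. The plasminogen activator PLAT had 8852 reads in SKHEP1 and 6 in HepG2, a ratio of 1160 (533 to 3162). The oxytocin receptor OXTR had 2486 and 2 reads, a ratio of 977 (270.3 to 8075). In full splice matches OXTR had 1314 and 2 reads, a log2 ratio of 9.04 against 9.93, and without isoforms with A-rich ends or the template-switching flag it had 925 reads in SKHEP1 and none listed in HepG2. TGM2 had 23970 and 56 reads, a ratio of 337 (259 to 446). Full splice matches held 7 of the 2864 MYOF reads in SKHEP1, too few for a call by the rule of 20 reads.

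All 10 genes furthest above SKHEP1 in HepG2 had no isoform listed in SKHEP1. ALB had 75514 reads, the fetal serum protein AFP 13473, the cell-surface proteoglycan GPC3 12011, the lipoprotein gene APOB 11555 and transferrin (TF) 11041. Full splice matches held 134 of the 11555 APOB reads. The protease inhibitor A2M had 8087 reads, the serum glycoprotein AHSG 6065, ITIH2 5328, the selenium carrier SELENOP 4847 and the fibrinogen chain FGG 3704.

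The fixed lists of hepatocyte genes stood far to the HepG2 side. Of 27 measured genes for hepatocyte secreted proteins, 25 were called higher in HepG2, 22 of them with no isoform listed in SKHEP1, and 0 in SKHEP1, with a median log2 ratio of SKHEP1 to HepG2 of -8.76 (percentile 0 of the random lists). ALB, AFP, APOB and TF led the list. Of 14 measured hepatocyte metabolism genes, 11 were called higher in HepG2, 9 of them with no isoform listed in SKHEP1. These included the asialoglycoprotein receptor genes ASGR1 (489 reads) and ASGR2 (676) and the glucuronosyltransferase gene UGT2B7 (249), none of them listed in SKHEP1. The tryptophan dioxygenase gene TDO2 was the 1 member called higher in SKHEP1, and the list median was -5.72 (percentile 0). Of 14 measured liver transcription factors, 11 were called higher in HepG2, 6 of them with no isoform listed in SKHEP1, and 1 in SKHEP1. Those higher in HepG2 included HNF4A (429 reads), PROX1 (314) and NR1H4 (229), which had no isoform listed in SKHEP1. The list median was -5.22 (percentile 0).

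Mesenchymal and adhesion genes stood on the SKHEP1 side. Of 28 measured mesenchymal markers, 22 were called higher in SKHEP1, 14 of them with no isoform listed in HepG2, with a median of 4.92 (percentile 100). VIM, LOXL2, CAV1 and the collagen gene COL3A1 (1168 reads) led the list. TAGLN was called higher in HepG2, and fibronectin (FN1), counted in the same list, had a log2 ratio of -1.32. Of 31 focal adhesion and contractile genes, 19 were called higher in SKHEP1, 6 of them with no isoform listed in HepG2, and 0 in HepG2, with a median of 2.62 (percentile 100). The integrin gene ITGA3 (1238 reads), CD44 and the annexin gene ANXA1 (2158) were listed in SKHEP1 alone. ANXA2 had 4026 reads in SKHEP1 and 59 in HepG2, a ratio of 53.7 (41.5 to 70.6).

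Epithelial markers were split, with most on the HepG2 side. Of 20 measured members, 11 were called higher in HepG2, 6 of them with no isoform listed in SKHEP1, and 2 (KRT7 and CLDN7, unlisted in HepG2) in SKHEP1, with a median of -3.31 (percentile 0). The adhesion gene EPCAM had 493 reads in HepG2 and 5 in SKHEP1, a ratio of HepG2 to SKHEP1 of 125.4 (53.4 to 388). The desmosome gene DSP had 371 and 10 reads, a ratio of 47.2 (25.4 to 99.2). The tight-junction gene CLDN4 (182 reads) and the splicing regulator ESRP2 (247) had no isoform listed in SKHEP1. Of the 7 members not called, the abundant keratin genes stood higher in SKHEP1. KRT8 had 5690 reads in SKHEP1 and 3450 in HepG2 (ratio 1.30, 1.24 to 1.35). KRT18 had 6262 and 1882 (2.62, 2.48 to 2.76), and KRT19 had 833 and 483 (1.36, 1.21 to 1.52). OCLN and JUP, also not called, stood higher in HepG2.

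Few endothelial markers were listed in either line. Of 26 genes in the list, 18 had no isoform listed in either library, and 6 were measured. Of these, 3 were called higher in SKHEP1, all with no isoform listed in HepG2: the co-receptor gene ENG with 359 reads, FLI1 with 59 and ROBO4 with 40. The junction gene ESAM was higher in HepG2, with 26 reads against 2 (ratio 16.5, 4.14 to 143.7). The list median was 3.15 (percentile 99.7). Over the 3 members listed in both lines, which leaves out ENG, FLI1 and ROBO4, it was -0.999 (percentile 17.8), the value of NOS3 with 14 and 22 reads. Markers of hepatic stellate cells were also few: of 6 measured, 3 were higher in SKHEP1 and 1 in HepG2, with a median of 2.40 (percentile 99.6). COL1A1 had 364 reads in SKHEP1 and none listed in HepG2, ALCAM had 4087 against 209, RGS5 had 34 against 4, and RELN had 310 reads in HepG2 alone. Of 4 measured blood cell markers, KIT (23 reads) was called higher in SKHEP1 and LYZ (568 reads) in HepG2. CD68 had a ratio of 1.11 (0.889 to 1.40), and the list median was 0.16 (percentile 57.3).

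**Figure D2:**
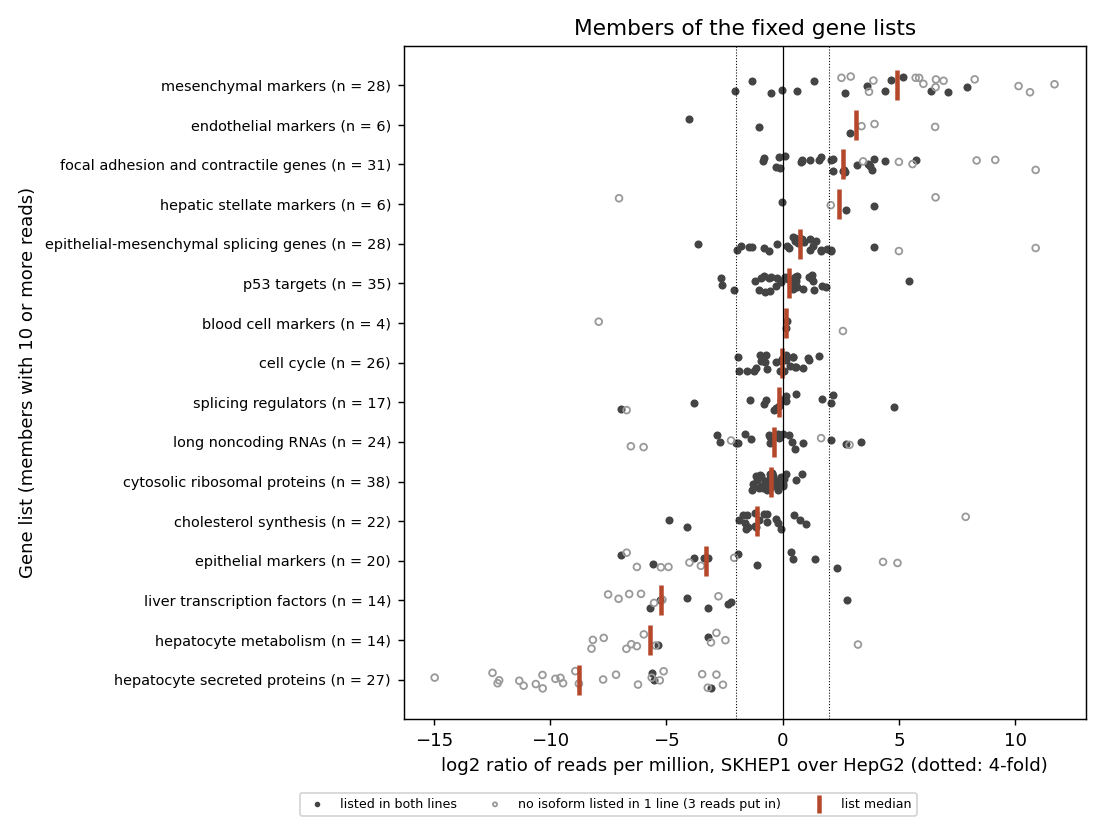
Each point is 1 gene of a fixed list with 10 or more reads in both libraries together, placed by its log2 ratio of RPM, SKHEP1 over HepG2. Open points had no isoform listed in 1 line and were placed with 3 reads there, vertical red marks are list medians, from -8.76 for hepatocyte secreted proteins to 4.92 for mesenchymal markers, and dotted lines mark 4-fold.

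Targets of p53 did not stand apart as a list. Of 35 measured members, PLK2 was at least 4-fold higher in SKHEP1 and 3 were higher in HepG2, with a median of 0.29 (percentile 89.3). PLK2, a polo-like kinase gene, had 4235 reads in SKHEP1 and 78 in HepG2, a ratio of 42.7 (34.1 to 54.1). The stress cytokine GDF15 was higher in HepG2 with a ratio of 6.03 (4.93 to 7.43), the death receptor gene TNFRSF10A with 6.36 (3.07 to 14.8) and SESN1 with 4.28 (3.31 to 5.59). Long noncoding RNAs were called in both directions, 3 each way of 24 measured, with a median of -0.36 (percentile 15.8). With full splice matches only, the median was -1.10 (percentile 0.515). CYTOR had 79 reads in SKHEP1 and 6 in HepG2 (ratio 10.4, 4.55 to 29.1), and MIR100HG had 28 reads in SKHEP1 alone. LINC00261 (218 reads) and HAGLR (149) were listed in HepG2 alone.

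Splicing regulators also differed one by one. Of 17 measured, 2 were higher in SKHEP1 and 3 in HepG2, with a median of -0.14 (percentile 36.5). RBFOX2 had 208 reads in SKHEP1 and 6 in HepG2, a ratio of 27.3 (12.3 to 75.1). MBNL3 had 194 reads in HepG2 and 2 in SKHEP1, and RBM47 had 22 and 2, while ESRP2 was listed in HepG2 alone. In the cholesterol synthesis list, 2 of 22 members were called higher in HepG2 and 1 in SKHEP1, with a median of -1.09 (percentile 0.08). The ratio of HepG2 to SKHEP1 was 29.3 (14.5 to 68.8) for TM7SF2 and 17.5 (9.98 to 33.5) for MVD. INSIG1, which retains the sterol sensor, had 893 reads in SKHEP1 and none listed in HepG2.

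None of the 26 cell cycle genes or the 38 cytosolic ribosomal protein genes reached 4-fold. The cell cycle median was -0.04 (percentile 35.8), and it turned to 0.05 with median-of-ratios scaling and to 0.18 after correction for isoform length. PLK1 had a ratio of HepG2 to SKHEP1 of 3.67 (3.28 to 4.10), CCNE1 of 3.82 (2.48 to 6.03) and PCNA of 2.92 (2.57 to 3.32), while CCNE2 was higher in SKHEP1 at 2.92 (1.84 to 4.79). The ribosomal median was -0.49 (percentile 3.32). RPL27, RPS12, RPS6 and RPS20 had the largest ratios in that list, with log2 values of -1.32, -1.29, -1.13 and -1.08. After correction for isoform length the ribosomal median was 0.04 (percentile 54.1).

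Genes listed in both lines numbered 9564 of 13248 (72.2%), with 2051 in SKHEP1 alone and 1633 in HepG2 alone. These numbers depend on depth. After SKHEP1 was thinned to 1876594 reads, it had 11262 genes, against 11615 before and 11197 in HepG2. The overlap was not recomputed at equal reads. Genes in 1 line alone had a median of 8 reads in SKHEP1 and 6 in HepG2, and 28 and 25 of them had 1000 reads or more, among them VIM and ALB. Among protein-coding genes 9199 were listed in both lines, 1647 in SKHEP1 alone and 1187 in HepG2 alone. Long noncoding genes numbered 234 in both lines, 290 in SKHEP1 alone and 323 in HepG2 alone. They held 0.364% of SKHEP1 reads and 0.458% of HepG2 reads. Sharing was not compared between gene types at matched read numbers.

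Structural categories were alike in the lines, with small differences, most of them beyond the intervals given, which treat isoforms of the same gene as independent. The shares were not recomputed at equal reads, so the greater read total of SKHEP1 may account for part of these differences. Full splice matches made up 36.2% of SKHEP1 isoforms (35.9 to 36.5) and 39.0% of HepG2 isoforms (38.7 to 39.4), and 81.2% and 82.9% of reads. Incomplete splice matches made up 19.6% (19.3 to 19.8) and 17.8% (17.6 to 18.1) of isoforms. New combinations of known splice sites made up 21.4% (21.2 to 21.7) and 22.1% (21.8 to 22.4). Isoforms with a splice site absent from the reference made up 20.9% (20.7 to 21.2) and 18.8% (18.5 to 19.04). Isoforms of 1 exon made up 4.63% (4.50 to 4.77) in SKHEP1 and 5.47% (5.32 to 5.63) in HepG2. A 3′ end followed by 60% or more A was found for 20.04% (19.8 to 20.3) and 19.1% (18.8 to 19.4) of isoforms, and the template-switching flag for 3.25% (3.14 to 3.37) and 3.46% (3.33 to 3.59). All junctions were canonical in 90.8% (90.7 to 91.0) and 92.3% (92.1 to 92.4) of multi-exon isoforms. A coding sequence was predicted for 94.2% (94.1 to 94.4) and 93.4% (93.2 to 93.6), and nonsense-mediated decay for 13.5% (13.3 to 13.7) and 12.5% (12.3 to 12.7) of those scored.

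Isoforms were longer in SKHEP1, and gene ratios followed isoform length. The median length was 3109 nt in SKHEP1 (interquartile range 2171 to 4210) and 2748 nt in HepG2 (1914 to 3816), with medians of 11 exons (6 to 17) and 10 exons (5 to 15). Weighted by reads, the median lengths were 3043 and 2591 nt, and the median exon number was 11 in both lines. Over 20 bins of genes by isoform length, the median log2 ratio went from -0.56 in the shortest bin to 0.60 in the longest. Corrected for that trend, 1242 genes were called higher in SKHEP1 and 1066 in HepG2, of which 1186 and 1000 were among those called without the correction.

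**Figure D3:**
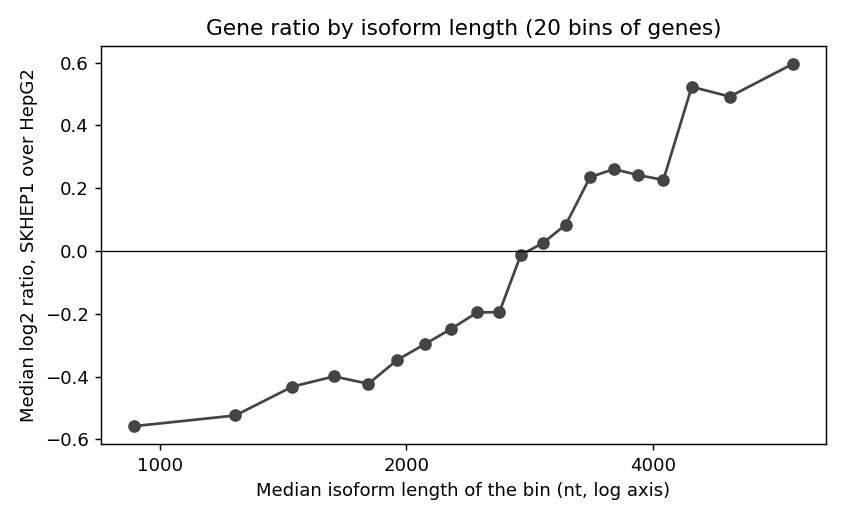
Points are 20 bins of genes with 10 or more reads in each library, with the median isoform length of the bin in nt on a log axis and the median log2 ratio of RPM, SKHEP1 over HepG2, on the vertical axis. The ratio goes from -0.56 at 931 nt to 0.60 at 5919 nt.

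In the 9564 genes listed in both lines, SKHEP1 had a mean of 8.88 isoforms for each gene and HepG2 7.51, with medians of 6 and 5. After SKHEP1 was thinned to 1876594 reads, it had 79258 isoforms against 79645 in HepG2, and the ratio of the means was 0.997. Isoforms left with fewer than 2 reads were dropped, so SKHEP1 kept 1862697 reads and its values are slightly low. Reads were also made equal gene by gene, in 6316 genes with 20 or more reads in each line. The means were then 8.04 isoforms in SKHEP1 and 8.60 in HepG2, a ratio of 0.935. The same dropping lowers the value of whichever line was thinned in a gene, so this ratio cannot settle which line has more isoforms. The heavy-chain myosin gene MYH9 had the most isoforms in SKHEP1 (293), and FN1 had the most in HepG2 (266). Of 22402 reference transcripts with a full splice match, 13007 (58.1%) were found in both lines, 5171 in SKHEP1 alone and 4224 in HepG2 alone. These transcript numbers were not recomputed at equal reads.

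Most genes had the same leading transcript in both lines. Of 5464 genes tested, 5180 (94.8%) had the same one, and 90 (1.65%, 1.34 to 2.02) met the rule for a difference of 50 points. All shares of transcripts here are shares of the gene's full-splice-match reads. The 8 largest differences were close to complete exchanges of the assigned reference transcript. In ACD, FAM83D and LAMTOR5, the leading transcripts of the lines have the same splice junctions in GENCODE release 29, so no difference in splicing is shown. FAM83D-202 held 381 of 381 full-splice-match reads in SKHEP1 and FAM83D-201 held 593 of 593 in HepG2. In ORC3 and SYVN1 the junctions differ by 3 nt. The shelterin gene ACD had 97.1% of these reads in ACD-214 in SKHEP1 and 100% in HepG2 in ACD-213. In PALM2AKAP2, 98.8% (97.8 to 99.4) of 771 full-splice-match reads in SKHEP1 were in PALM2AKAP2-204 and all 70 in HepG2 in PALM2AKAP2-201, which differ in their exons. The splicing factor gene RBM10 had 83.9% (79.4 to 87.6) of its full-splice-match reads in SKHEP1 in RBM10-203 and all 53 in HepG2 in RBM10-206, which has another number of exons. MDH1-216 held 98.8% of full-splice-match MDH1 reads in SKHEP1 and MDH1-201 held 98.4% in HepG2. The junctions of these MDH1 transcripts could not be compared.

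In the epithelial-mesenchymal splicing list, 19 genes were tested and 1 met the rule. EPB41L5-201 held 24 of 28 full-splice-match reads of EPB41L5 in SKHEP1 (85.7%, 68.5 to 94.3) and 64 of 288 in HepG2 (22.2%, 17.8 to 27.4). The tropomyosin transcript TPM1-206 led in both lines, with 97.6% of full-splice-match TPM1 reads in SKHEP1 (97.1 to 98.0) and 53.9% in HepG2 (47.6 to 60.1). PKM-202 held over 99.9% of full-splice-match PKM reads in each line. By gene level, 5 of 28 measured members of this list were called higher in SKHEP1, 2 of them with no isoform listed in HepG2, and 1 (EPB41L5) in HepG2, with a median of 0.74 (percentile 99.5). With full splice matches only, the median was 0.46 (percentile 93.7), inside the central 95% of random lists. TPM1 had a ratio of 15.2 (13.4 to 17.3), and TPM2, with 122 reads, was listed in SKHEP1 alone, as was CD44.

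Isoforms outside the reference held 12.6% of reads in SKHEP1 (12.5 to 12.6) and 10.7% in HepG2 (10.7 to 10.8). The most abundant in SKHEP1 was an isoform of the aminopeptidase gene ANPEP with 16846 of 19081 reads (88.3%, 87.8 to 88.7). It was followed by isoforms of CAPN2 (4882 reads, 86.6% of the gene), ANLN (2224, 41.1%), MYOF (2087, 72.9%) and GARS1 (1366, 96.7%). All of these contained a non-canonical junction. In HepG2, isoforms with such a junction also held 100% of CAPN2 and GARS1 reads and 99.2% of ANLN reads, but 1.88% of ANPEP reads. Without ANPEP the SKHEP1 share was 11.9%. The most abundant in HepG2 were isoforms of NCL (2319 reads, 30.2% of the gene), HADHA (946, 87.8%), BSG (827, 92.7%), HNRNPM (551, 42.7%) and IMMT (538, 64.0%). Those of BSG and HNRNPM had canonical junctions only. In SKHEP1, isoforms with a non-canonical junction held 98.7% of IMMT reads, but 1.76% of NCL and 0.250% of HADHA reads.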

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

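The PURPL test below was chosen after the result was seen. The isoforms given first stand here because the gene comparisons do not use them and they held reads. Isoforms joining 2 or more annotated genes held 2159 reads in SKHEP1 and 1246 in HepG2. Intergenic isoforms held 2268 reads in SKHEP1 and 2439 in HepG2, and antisense isoforms held 1581 and 1719. Of the intergenic isoforms, 68.8% in SKHEP1 and 79.8% in HepG2 ended before sequence with 60% or more A.

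An isoform of 1 exon antisense to PURPL had 4 reads in HepG2 (2242 nt long), and a similar one had 3 reads in SKHEP1 (2508 nt). In both, the 3′ end was followed by 100% A. The authors' PURPL sheet includes it.

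The 2-exon PURPL isoforms were the most abundant class in both lines, and 33 of their 51 reads (64.7%, Wilson interval 51.0 to 76.4) ended with no poly(A) signal in the table. All 33 came from a single end site, 4399 nt before the nearest annotated gene end, with 14 reads in SKHEP1 and 19 in HepG2. The remaining 2-exon reads ended elsewhere and carried a signal. For the other PURPL isoforms this was 6 of 79 reads (7.59%, 3.53 to 15.6). Among all isoforms, a signal was missing from 74.9% in SKHEP1 and 75.8% in HepG2 where 80% or more A followed, and from 5.63% and 5.87% where under 60% A followed. A candidate explanation is priming inside a longer transcript, at a genomic A stretch. A true end at the same place in both lines remains open, since both lines share that stretch and no biological explanation was tested.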

How the results depend on the processing

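Lengths without the most abundant genes, list medians over members listed in both lines, the length correction, PURPL without A-rich ends and the junction limit were chosen after seeing the data. Of 47 alternative values for the comparisons, 28 stayed within their limits, 17 moved and 2 reversed. The 2-read minimum removes nothing. Those counted as reversed were the ratios of SKHEP1 to HepG2 after thinning, for isoforms (1.19 to 0.995) and isoforms per gene (1.18 to 0.997). Both came close to equality at equal library totals, which the removal of reads accounts for. A HepG2 excess is neither shown nor excluded, since the ratio at equal reads in each gene was 0.935, with the limit given above. The cause of the other shifts was not tested. Without A-rich or template-switch isoforms the isoform ratio was 1.18 and the SKHEP1 excess of reads outside the reference was 2.29 points, against 1.83. The full-splice-match difference, SKHEP1 minus HepG2, was -2.87 points, -1.73 by reads and -3.76 from 5 reads. The A-rich excess in SKHEP1 was 0.962 points, 0.413 at 80% A and 1.44 for multi-exon isoforms. The length difference of 361 nt was 452 by reads and 400 by reads without the 10 most abundant genes of each library. Genes in both lines were 73.6% for multi-exon isoforms. A minimum of 50 reads left 838 genes higher in SKHEP1 and 745 in HepG2, and a 2-fold limit gave 2211 and 2164 genes. With full splice matches only, 961 of 1285 calls in SKHEP1 and 829 of 1113 in HepG2 remained, and 3 genes were called the other way. Shared transcripts were 61.9% from 5 reads and 55.9% with incomplete matches. Leading transcripts differed in 54 genes from 50 reads, in 150 at 30 points and in 55 with junctions over 5 nt apart or another exon number. Over members listed in both lines the endothelial median went from 3.15 to -0.999 (3 members, percentile 17.8). That selection removes the members listed in SKHEP1 alone, and the value lies inside the central 95% of random lists. The others were -5.53 for hepatocyte secreted proteins (3), -4.27 for metabolism (2), -3.23 for liver transcription factors (7), -1.93 for epithelial, 3.15 for mesenchymal, 2.09 for focal adhesion, 2.74 for stellate, -1.16 for cholesterol, 0.60 for epithelial-mesenchymal splicing, -0.19 for noncoding RNAs and -0.12 for splicing regulators, and no member changed for p53 targets, ribosomal proteins and cell cycle. Of the lists, 8 then lay outside the central 95% of random lists, against 10, and the metabolism and blood cell lists (median 0.16, 2 members) had too few members for a percentile. PURPL ratios of HepG2 to SKHEP1 lay between 1.02 and 1.71, and the read number limits them. Of the 20 genes named by ratio, 17 had no isoform in the other line, so their alternative values rest on the 3 reads put there and test little. Of 80 such log2 values for the 20 genes, 1 fell under the 4-fold limit, MYOF from 9.55 to 0.91 with full splice matches only, which is 7 reads against that 3. With full splice matches only APOB went from -12.26 to -5.80 (134 reads against that 3), PLAT from 10.18 to 11.16 (8573 reads against that 3) and OXTR from 9.93 to 9.04. Without A-rich or template-switch isoforms OXTR fell to 7.95 (925 reads against that 3), and MYOF fell to 8.96 with the length correction.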

Other observations

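The test of junctions over all compared genes and the length test without the most abundant genes were chosen after part of the data had been seen, as were the genes named here. PEG10, IGF2 and the RNA-binding, reductase and cytokine genes below belong to no fixed list, and their groups were not tested. PEG10, an imprinted gene derived from a retrotransposon, was 24.3-fold higher in HepG2 than in SKHEP1 (12809 and 670 reads), and the growth factor IGF2 was 69.1-fold higher (7665 and 141 reads). The RNA-binding protein gene LIN28B (485 reads) and DLK1 (201 reads) were listed in HepG2 alone, and IGF2BP1, which also binds RNA, was 3.12-fold higher there (800 and 326 reads). Of the reductase and dehydrogenase genes looked at, NQO1 (1325 reads), AKR1C1 (1312), AKR1B10 (302), AKR1C3 (230) and ALDH1A1 (1651) were listed in HepG2 alone, and UGDH was 13.5-fold higher there (5434 and 511 reads).

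Among the cytokine genes looked at, CXCL1 (697 reads), IL1B (351) and IL6 (14) were listed in SKHEP1 alone, and CXCL8 had 278 reads in SKHEP1 and 14 in HepG2, a ratio of 15.6 (9.15 to 28.9).

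Isoforms predicted to undergo nonsense-mediated decay held 9.89% of scored reads in HepG2 and 6.73% in SKHEP1. In HepG2 they included 99.0% of ALB reads and 95.6% of AFP reads. The most abundant ALB isoform, a full splice match of ALB-201, alone held 96.0% of ALB reads. Without ALB and AFP the HepG2 share was 5.34%, against 6.73% in SKHEP1, so the HepG2 excess rests on these genes. The flag is a prediction, and decay was not measured. ALB was the most abundant gene in HepG2 (4.02% of reads), so the flag is no evidence that its RNA is degraded.

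Isoforms were longer in SKHEP1, and among 5952 transcripts with 20 or more reads in each library, the mean 3′ end lay 200 nt or more further downstream in SKHEP1 for 666 and in HepG2 for 76 (89.8% in SKHEP1, 87.4 to 91.7). Most transcripts shifted little: over all 5952 the median shift was 2.57 nt at the 3′ end and 12 nt in length. These medians are small beside the difference of 361 nt in median isoform length. A few abundant HepG2 genes are argued against, since the read-weighted difference in length was 452 nt with all genes and the value without the 10 most abundant genes of each library was 400 nt. Depth is argued against by a difference of 352.5 nt at equal reads, against 361 nt. Length selection during library making may account for part. After HepG2 isoforms were reweighted by the trend of gene ratios with length, the counts were 375 in SKHEP1 and 145 in HepG2, and the median 3′ shift was 0 nt. Of these shifted transcripts, 72.1% (68.1 to 75.8) ended further downstream in SKHEP1. That share lies between the limits set beforehand. For the shifted transcripts, length selection and a difference between the lines in 3′ end choice therefore cannot be told apart with 1 library each.

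Examples of a 3′ end further downstream in SKHEP1 are PHLDA1-203, by 1372 nt with 5448 and 1185 reads, and EIF2AK1-201, by 1381 nt with 55 and 695 reads. The opposite held for TAPBP-202, whose mean 3′ end stood at -1578 nt from the reference end in SKHEP1 (22 reads) and at -20.7 nt in HepG2 (307 reads).

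Exchanges of the leading transcript were partly between near-identical models. Of 80 genes whose leading transcripts could be compared in GENCODE release 29, 25 (31.2%, 22.2 to 42.1) had junctions within 5 nt of each other. Merging of near-identical junctions when isoforms were collapsed could hide 1 member of such a pair, and it is argued against for the set as a whole, since 55 of the 80 differed by more or in exon number. For the close pairs the question stays open: within a library, both members of a reference pair were listed for 54.6% (46.9 to 62.1) of 163 pairs within 5 nt, and for 82.9% (79.8 to 85.6) of 660 pairs that differ by 6 to 30 nt. The line difference itself was not tested, because each line has 1 library.

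Isoforms with a non-canonical junction held most reads of some genes. Of 4364 genes with 50 or more reads in each library, 93 had over 50% of their reads in such isoforms in both lines, among them CAPN2, ANLN, GARS1 and IMMT. In 14 genes the share differed by 50 points or more. ANPEP had 91.7% in SKHEP1 and 1.88% in HepG2, and HADHA had 0.250% and 88.0%.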
